A study of Mus musculus with 8 samples.

How the data were processed

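Lineage-depleted bone marrow cells of 4 Runx1 Δ/Δ mice were cultured for 2 days with SCF (50 ng/ml), Flt3 ligand (100 ng/ml), IL-11 (100 ng/ml) and IL-3 (10 ng/ml) and then transduced with a retrovirus carrying a Pcgf1 or a control shRNA. Puromycin (5 µg/ml) was added 24 h after transduction and kept for 36 h. From each of the 8 cultures 400 ng of total RNA were labelled with Cy3 and hybridised to a one-colour Agilent whole mouse genome array. Per the submitters' processing notes the arrays were read with Agilent Feature Extraction 10.1. The arrays filled 2 slides of 4, mice 1 and 2 on 1 slide and mice 3 and 4 on the other, and the scan batch was identical to the slide, so each slide held both groups.

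Per the file headers, the deposited spot files give the intensity of each spot after local background subtraction and spatial detrending, with no normalization between arrays, beside the raw median spot and background intensity and flags for spots well above background, saturated or non-uniform. The authors' deposited value table holds log2 values, which were checked against the spot files. Over 13321 bright probes the differences between its columns followed the spot files with r of 1.00 and a slope of at least 0.998, up to 1 shift per array close to that of the 75th percentile, and each probe was centred on its median over the 8 arrays after low values were raised to a floor. Its column medians were 0.05 and 0.10 (control and Pcgf1 shRNA of mouse 1), 0.11 and −0.05 (mouse 2), 0.10 and −0.11 (mouse 3), and −0.13 and −0.20 (mouse 4). The spot files were used for the results and the value table as an alternative.

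The log2 of the processed intensity was shifted on each array so that the 75th percentile of the non-control spots was 0. Control spots were left out, as were 242 values of spots marked as non-uniform, and spots of the same probe were averaged. A probe was kept when it was well above background on all 4 arrays of at least 1 group, which left 22747 of 41174 probes. Of the 41174 probes 24375 were named by matching their RefSeq accession to an annotation of GRCm38.p6, and the other 16799, among them 1528 whose RefSeq accession had no match, kept their own identifier. The probe with the highest mean signal stood for a gene, which gave 17302 genes, 11743 of them with a symbol, and 17301 with a test. Where a gene was above background on 0 arrays of a group, its change is given as a bound against the lowest signals called above background (log2 −5.94 to −5.22, by array).

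Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, adjusted p 0.05) without a block. The fit with mouse as a block, for which each culture was paired with the other culture of the same animal, stands beside it, since the labels name no test. Gene lists were tested with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over 28 lists with at least 5 measured genes; 50 genes with a left-out value were not used), with a correlation estimated for each list, and with fry. The 28 lists covered PRC1.1 members, other Polycomb genes, Hox genes and cofactors, developmental regulators silenced by Polycomb in stem cells, CDK inhibitors, haematopoietic stem cells, neutrophil primary granules, neutrophil maturation, monocytes and macrophages, mast cells and basophils, eosinophils, erythroid cells, megakaryocytes and platelets, B cells, T and NK cells, dendritic cells and MHC class II, stroma and endothelium, the cell cycle, p53 targets, the interferon response, ATF4 and ER stress, immediate early and heat shock genes, inflammatory cytokines, cholesterol synthesis, glycolysis and hypoxia, ribosomal proteins, cytokine receptors, and core binding factor and haematopoietic transcription factors. The Pcgf1 values and the list medians were also compared by exact permutation tests.

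The main test, the lists and the rule for naming genes were set before the data were examined. The rule takes Pcgf1, Runx1, the 12 genes with the largest rise and the 12 with the largest fall among genes that passed and changed the same way in all 4 mice, the 4 members of each list with the smallest p, and every measured Hoxa gene and PRC1.1 member. Genes named outside this rule are said to have been chosen after their values were seen. Transcripts without a symbol were counted but not named, and some genes that the rule takes are not described here.

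The procedure was tested on simulated data made from these arrays with known changes. At a log2 change of 0.5, 1 and 2 the fit without a block recovered 28.4%, 63.6% and 86.4% of the changed genes, and 3 of 16995 unchanged genes were called. With mouse as a block the shares were 32.8%, 77.3% and 90.9%, and 2 unchanged genes were called. The simulated genes varied independently of each other. These shares and false calls therefore do not cover the correlation between genes in the real arrays. Alternatives covered the block, slide, normalization, background, filter, probe choice, value table, variance model, array weights, thresholds and left-out mice and arrays. Normexp background correction started from the median spot and background intensity. The values were handled in R (data.table version 1.17.8) and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.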

Results

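Messenger RNA was profiled on 8 one-colour whole-genome arrays, 1 for each of 8 cultures of mouse haematopoietic stem and progenitor cells (HSPCs). The cells came from the bone marrow of 4 mice of the genotype Runx1 Δ/Δ on a mixed C57Bl/6 and 129SvJ background. Runx1 encodes a DNA-binding subunit of core binding factor, a transcription factor of blood formation. From each mouse 1 culture was transduced with a retroviral shRNA against Pcgf1 and 1 with a control shRNA, so each group held 4 arrays. Pcgf1 encodes a subunit of PRC1.1, a Polycomb complex that ubiquitinates histone H2A and represses developmental genes. On each array 54.8% to 62.0% of the 43379 non-control spots were well above background, the 75th percentile of the processed signal lay between 519 and 854, and 0 spots were saturated. With 4 arrays per group, the number of arrays limits the precision of every value given here.

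Cultures of the same mouse resembled each other. With each group's mean removed, the 2 arrays of a mouse correlated across genes with r of 0.44, 0.48, 0.41 and 0.64 in mice 1 to 4, higher in each case than with any array of the other group from another mouse (genes are not independent replicates). Both arrays of mouse 4 lay apart on the first principal component (38.2% of the variance), at 44.8 and 38.3 against −30.1 to 2.9 for the other 6 arrays. On the second component (28.3%) the array with the Pcgf1 shRNA lay below the control array in 4 of 4 mice.

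The design asks which transcripts change when Pcgf1 is reduced in cells of the genotype Runx1 Δ/Δ. Knockdown left 39.0% of the Pcgf1 transcript, with 37.8% to 41.0% in the individual mice. In these cells 4 Hoxa genes, the progenitor marker Cd34 and the transcription factor gene Sox4 rose, while neutrophil genes such as Ngp, Fpr1, Fpr2 and Fcnb fell 3.38-fold or more. The haematopoietic stem cell list, which holds Cd34, did not move as a whole (median 0.02, 14 members higher and 11 lower). The neutrophil maturation list was lower as a group, with a median log2 change of −0.60, and so were lists for eosinophils, erythroid cells, monocytes, dendritic cells and B cells. The B cell list was dim on every array, with median log2 signals of −4.46 to −3.38. The neutrophil primary granule list, which also holds genes that encode no granule protein, was slightly higher instead, with a median of 0.30. None of these list calls held with an estimated correlation, where the lowest adjusted p was 0.181.

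The Pcgf1 transcript (chromosome 6, 83077552 to 83080855, assembly GRCm38.p6) had a mean log2 signal of −0.23 ± 0.18 (SD, n = 4) with the control shRNA and −1.59 ± 0.17 (n = 4) with the Pcgf1 shRNA. The log2 change was −1.36 (SE 0.12), with an adjusted p of 0.0197, or 0.0139 with mouse as a block. An exact two-sided permutation test of the 4 against 4 values, which ignores the pairing by mouse, gave p = 0.0286, the smallest its design allows. An exact sign-change test of the 4 within-mouse differences cannot reach 0.05; it gave its smallest p of 0.12. The change was −1.40 on the slide of mice 1 and 2 and −1.31 on the slide of mice 3 and 4. Its size held when both arrays of mouse 1, 2 or 3 were left out (−1.34, −1.34 and −1.38) but the limma call without a block did not (adjusted p 0.113, 0.352 and 0.0904). Runx1 read 0.70 ± 0.22 and 0.97 ± 0.18 (log2 change 0.27, adjusted p 0.473); where its probe lies relative to the deleted part is not given in the sources used here, so the value checks nothing about the deletion.

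Among the 9 measured members of PRC1.1, Pcgf1 fell and Bcorl1, which encodes a corepressor subunit of the complex, rose (log2 change 0.50, SE 0.08, adjusted p 0.0339, 0.0298 with mouse as a block). The other 7 did not pass. Bcor, the paralogue of Bcorl1, stood at 0.38 on the brightest of its 3 probes (adjusted p 0.0900, 0.0423 with mouse as a block) and at −0.16 on another, Rnf2 at 0.34, Kdm2b at 0.33, Skp1 at 0.21, Yaf2 at 0.15, Rybp at 0.05 and Ring1 at −0.22. Adjusted over the list alone, 4 members rose and 2 fell. The median of the list was 0.21, with a camera adjusted p of 0.0329 that was lost both with mouse as a block (0.0983) and with an estimated correlation (adjusted p = 0.367 with an estimated correlation). The list includes Pcgf1, the target of the shRNA. Its fall enters these tests and the list mean of 0.04, so they do not describe the other members alone. Of the 27 measured genes of other Polycomb complexes 0 passed, or 1 that rose and 1 that fell adjusted over the list alone; the list median was 0.10 (adjusted p 0.0131; adjusted p = 0.450 with an estimated correlation). The smallest p values in it were those of Scmh1 (0.40), Jarid2 (−0.34), Cbx8 (0.57) and Pcgf6 (0.33).

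Of the 17301 genes with a test, 132 passed an adjusted p of 0.05 without a block, 103 higher and 29 lower with the Pcgf1 shRNA, and 2103 had an unadjusted p under 0.05. A fold of 2 or more was reached by 29 of the higher and 15 of the lower genes. With mouse as a block 921 genes passed, 503 higher and 418 lower, among them all 132; rises made up 78.0% of the calls without the block and 54.6% with it. With slide as a block 157 passed, 109 higher and 48 lower, which held 87 of the 103 and 27 of the 29. Of the 103 higher genes 7 were above background on 0 control arrays. Without a block limma called 1, 0 and 0 genes when both arrays of mouse 1, 2 or 3 were left out (1673, 1000 and 1089 at an unadjusted p under 0.05), and 363 without mouse 4. With mouse as a block it called 284, 0 and 306 genes without mouse 1, 2 or 3 (2435 at an unadjusted p under 0.05 without mouse 2). Without mouse 4 it called 145 with the block, 118 higher and 27 lower. Rises then made up 81.4% of the calls with the block and 68.3% without it, so the near balance with the block depended on mouse 4. Without the filter on dim probes 0 of 32969 genes passed (2199 unadjusted), with normexp background correction 72 passed (48 higher and 24 lower, 66.7% higher), and with array weights 1229.

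Hox genes set positional identity in the embryo and help to keep early blood progenitors undifferentiated, and 4 genes of the Hoxa cluster rose. Hoxa10 was above background on 0 of 4 control arrays and on 4 of 4 with the Pcgf1 shRNA, at least 2.22-fold higher (fitted log2 change 2.34, SE 0.38, adjusted p 0.0419, 0.0139 with mouse as a block). Hoxa7 rose from −0.39 ± 0.42 to 1.29 ± 0.24 (n = 4 each), 3.19-fold (adjusted p 0.0206, block 0.0139). Hoxa9, which has Meis1 as a cofactor in leukaemia, rose from −2.01 ± 0.44 to −0.56 ± 0.20, 2.74-fold (adjusted p 0.0287, block 0.0190). Hoxa4 rose by 0.90 on the log2 scale (SE 0.10, adjusted p 0.0206, block 0.0167). Each rose in 4 of 4 mice.

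The rise was not shared by the whole Hoxa cluster. Hoxa5, which lies between Hoxa4 and Hoxa7, was 1.73 higher (SE 0.37) but passed only with mouse as a block (adjusted p 0.0905 without it, 0.0477 with it), and 1 of 4 control arrays was above background. Hoxa3 (−0.08, adjusted p 0.946) and Hoxa6 (0.13, adjusted p 0.859; −0.08 with normexp) did not pass either way. The genes named here run along chromosome 6 from Hoxa3 (start 52169059) to Hoxa10 (end 52240854). Outside the cluster Pbx2, which encodes a Hox cofactor, fell by 0.51 on the log2 scale (adjusted p 0.0264, block 0.0257), and Meis1 (0.79) and Hoxb2 (0.94), chosen after their values were seen, passed only with the block (0.0318 and 0.0445).

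Of the 17 measured genes of the Hox list 4 rose and 1 fell, and adjusted over the list alone 9 rose and 1 fell; because Hox genes were already of interest in the study of these cells, this list is not independent evidence of its direction. The list median was 0.55, also with Hoxa10 at its bound, and 0.38, 0.67, 0.92 and 0.55 in mice 1 to 4. Camera gave an adjusted p of 1.35e-05 (adjusted p = 0.181 with an estimated correlation).

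**Figure D1:**
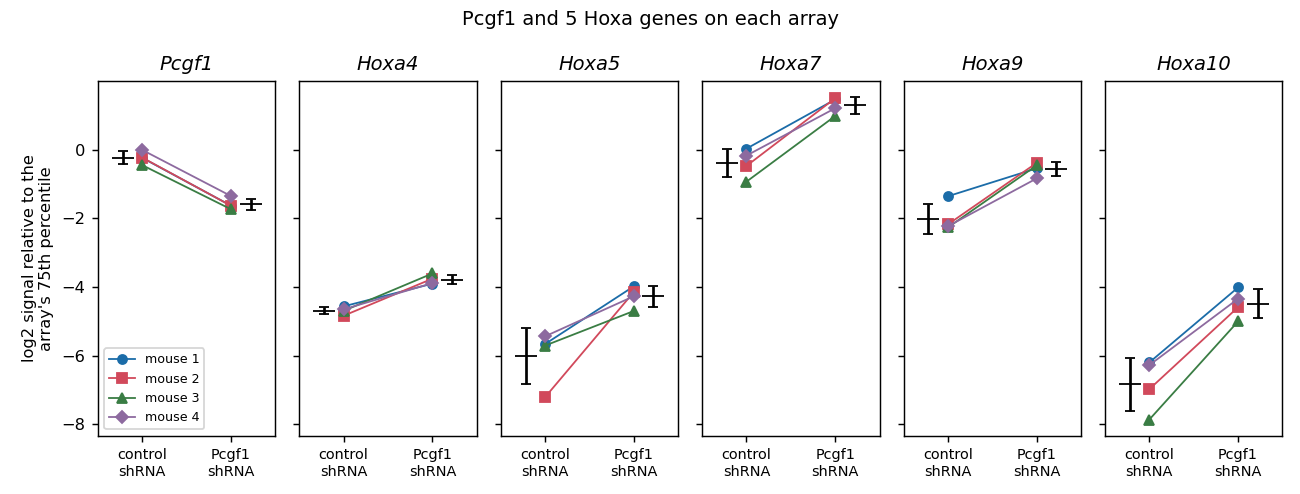
Log2 signal of Pcgf1 and of 5 Hoxa genes on each of the 8 arrays, relative to the array's 75th percentile. Lines join the 2 cultures of a mouse, and black bars give the mean ± SD of 4 arrays. Pcgf1 is lower with the Pcgf1 shRNA in 4 of 4 mice and each of the 5 Hoxa genes is higher in 4 of 4, of which Hoxa5 did not pass without a block. The control values of Hoxa10, and most of those of Hoxa5, were not above background.

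Large rises were also found outside the Hox list. Jam3, a junctional adhesion molecule of stem cells and endothelium, rose 3.08-fold, Ltbp3, which binds latent TGF-beta, 2.93-fold (on the brighter of 2 probes; the other changed by 0.11 on the log2 scale), and Gdf11, a TGF-beta family ligand, 3.00-fold with 2 of 4 control arrays above background. B4galnt4 rose 2.56-fold, Fgd1 2.53-fold and Rtn4r, the Nogo receptor, 2.45-fold. Btbd11, Vash2 and L3hypdh were above background on 0 control arrays and were at least 2.16-fold, 1.91-fold and 1.70-fold higher. Adjusted p values of these 9 genes lay between 0.0197 and 0.0467 and all 9 rose in 4 of 4 mice; Btbd11 did not pass with slide as a block (0.0522).

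Genes of maturing neutrophils were among the genes that fell. Ngp, a protein of secondary granules, was above background on 4 of 4 control arrays and on 0 of 4 with the Pcgf1 shRNA, at least 3.38-fold lower (fitted log2 change −3.44, SE 0.50, adjusted p 0.0287, block 0.0342). The formyl peptide receptors Fpr1 and Fpr2, which guide neutrophils to bacteria, fell by 2.53 and 1.79 on the log2 scale (adjusted p 0.0471 and 0.0264, block 0.0149 for each). Stfa3, a stefin of granulocytes, fell by 2.61 (adjusted p 0.0288) and Fcnb, a ficolin of granules, by 1.80 (adjusted p 0.0365). Ly6c1 fell by 1.17 (adjusted p 0.0458) and Cybb, the catalytic subunit of the phagocyte oxidase, by 0.85 (adjusted p 0.0264). Each was lower in 4 of 4 mice. Stefin, Ly6 and formyl peptide receptor genes have close paralogues that 1 probe may not separate.

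Of the 32 measured genes of neutrophil maturation 7 fell and 0 rose without a block, 15 fell and 0 rose adjusted over the list alone, and 16 fell and 1 rose with mouse as a block. Among members chosen after their values were seen, the alarmin genes S100a8 (−1.78) and S100a9 (−2.48), the cathelicidin gene Camp (−1.80) and Ltf (at least 5.10-fold lower, with 0 of 4 arrays with the Pcgf1 shRNA above background) passed only with the block (0.0185, 0.0219, 0.0266 and 0.0243), as did Cxcr2 in the other direction (0.54, 0.0194). The list median was −0.60, also with Ngp and Ltf at their bounds, and −0.49, −0.63, −0.91 and −0.66 in mice 1 to 4 (camera adjusted p 5.15e-10; adjusted p = 0.450 with an estimated correlation). The primary granule list went the other way. Its 16 genes include granule proteins such as Mpo and Elane, but also genes that encode none, such as Cebpa, Gfi1 and Myb. Of the 16, 0 passed, 5 rose adjusted over the list alone, and the list median was 0.30 (camera adjusted p 0.00241, or 0.583 with an estimated correlation). With mouse as a block 3 passed, Gfi1 (0.79, 0.0326), Cebpa (0.70, 0.0212) and Igfbp4 (0.53, 0.0398), none of which encodes a granule protein. Fut8 (0.72) had an adjusted p of 0.0523 with the block. The difference between the medians of both lists within a mouse, primary granule minus maturation, was 0.92 ± 0.24 (mean ± SD, n = 4 mice).

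**Figure D2:**
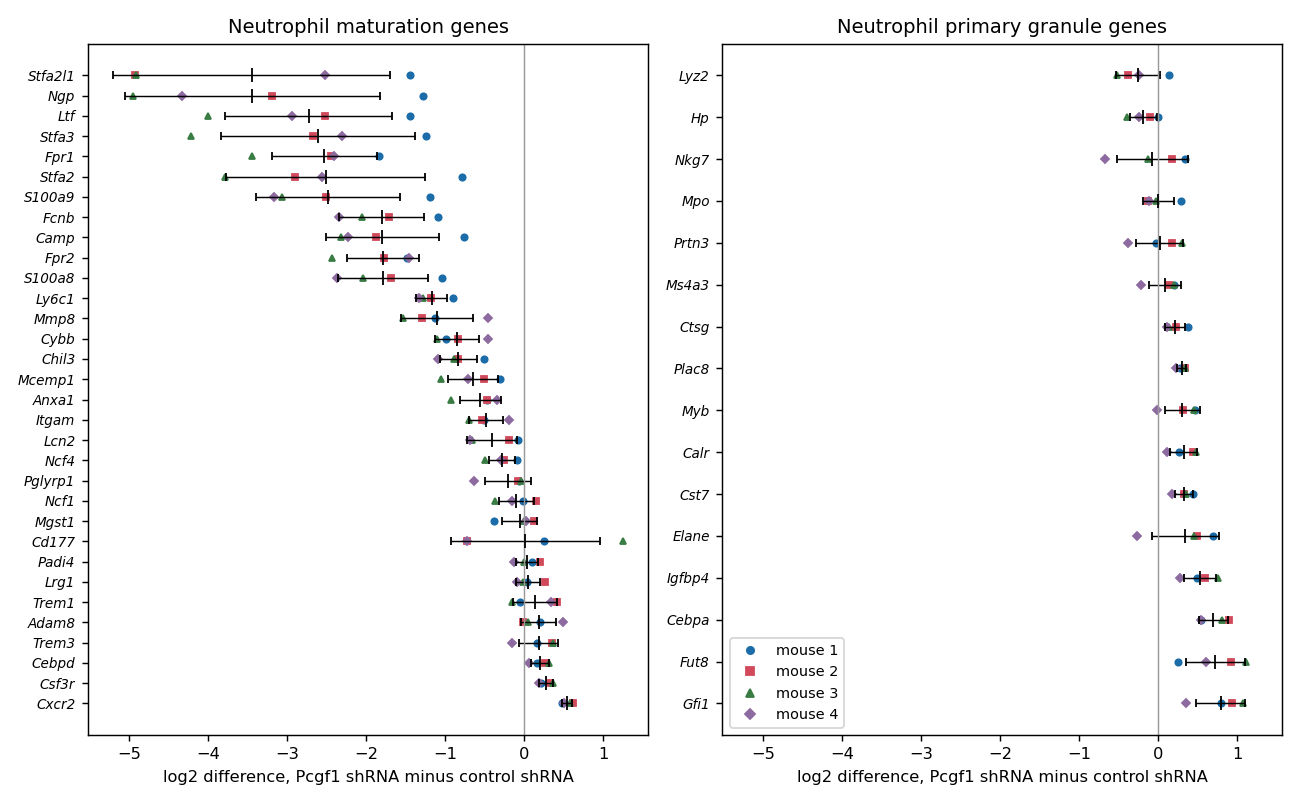
Log2 difference between the Pcgf1 shRNA culture and the control shRNA culture of each mouse. Shown are the 32 measured neutrophil maturation genes and the 16 measured genes of the primary granule list. Coloured points are mice, and black bars give the mean ± SD of 4 mice. Of the maturation genes 23 have a mean below 0, and of the primary granule list 12 have a mean above 0.

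Other mature blood lineages were lower as lists, mostly without single genes that passed. Of the 23 mast cell and basophil genes, the tryptase gene Tpsb2 (log2 change −1.71, adjusted p 0.0467, block 0.0257) and Tph1, the first enzyme of serotonin synthesis (−1.37, adjusted p 0.0206, block 0.0167), fell, 3 fell adjusted over the list alone, and Mcpt4 (−1.27, adjusted p 0.0791, block 0.0164) and Hs6st2 (−0.47, block 0.0499) passed only with mouse as a block, with which 7 fell and 0 rose; the list median was −0.16 (adjusted p 0.0190; adjusted p = 0.450 with an estimated correlation). Of the 15 B lymphoid genes Pou2af1, a B cell coactivator, fell by 1.08 on the log2 scale (adjusted p 0.0354, block 0.0149), and 2 fell adjusted over the list alone. Mzb1 (−1.02, adjusted p 0.0569, block 0.0438) and Spib (−0.72, block 0.0294, chosen after its values were seen) passed only with mouse as a block. Vpreb1 (0.39) did not pass. The median change of the B lymphoid list was −0.29 (camera adjusted p 0.00108, or 0.181 with an estimated correlation). Its median signal on each array was low, log2 −4.46 to −3.38, where the lowest signals called above background were −5.94 to −5.22.

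Among the 9 eosinophil genes 0 passed, but the granule proteins Prg2 (−1.87, block 0.0350) and Prg3 (−1.70, block 0.0208) and the ribonuclease Rnase2a (−1.85, block 0.0429) passed with mouse as a block, as did the receptor gene Il5ra in the other direction (0.51, 0.0476). Adjusted over the list alone 5 fell and 1 rose. The list median was −1.26, −0.61 on the slide of mice 1 and 2 and −1.91 on that of mice 3 and 4 (adjusted p 0.00108; adjusted p = 0.367 with an estimated correlation).

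Of 31 erythroid genes 0 passed without a block, also adjusted over the list alone. With the block 7 fell, or 27 adjusted over the list alone. Among the 7 were Ermap (−1.53, 0.0310), the transferrin receptor Tfrc (−0.36, 0.0485) and Klf1 (−1.05, 0.0483, chosen after its values were seen). Slc4a1 (−1.05) and Add2 (−0.90) did not pass over all genes. The median of the erythroid list was −0.74, with −0.29, −1.04, −1.29 and −0.44 in mice 1 to 4 (camera adjusted p 1.14e-06, or 0.583 with an estimated correlation). Monocyte and macrophage genes had 33 measured members, and 0 passed without a block, also adjusted over the list alone. With the block 8 fell, or 23 fell and 1 rose adjusted over the list alone. Among the 8 were Klf4 (−1.26, 0.0391), Irf8 (−0.47, 0.0485) and Ccr2 (−1.21, 0.0335), while Mpeg1 (−0.77) did not pass over all genes. The list median was −0.52 (camera adjusted p 1.14e-06, or 0.450 with an estimated correlation). Of 26 dendritic cell and MHC class II genes 0 passed without a block, also adjusted over the list alone. With the block 7 fell, among them H2-DMb1 (−0.41, 0.0342) and H2-DMa (−0.42, 0.0455), and Mgl2 rose (0.55, 0.0280, chosen after its values were seen). Adjusted over the list alone 16 fell and 1 rose with the block. Itgax (−1.08) and Cd86 (−0.55) did not pass over all genes, and the list median was −0.41 (camera adjusted p 0.00108, or 0.450 with an estimated correlation). Of 22 inflammatory cytokine and chemokine genes 0 passed and 1 fell adjusted over the list alone; with the block Il18 fell (−1.41, 0.0266) and Osm rose (0.51, 0.0331; chosen after its values were seen), Il1b (−1.26), Il6 (−0.45) and Tnfaip3 (−0.41) did not pass, and the median was −0.32 (adjusted p 0.00317; adjusted p = 0.583 with an estimated correlation). Of the 7 CDK inhibitors 0 passed and 2 fell adjusted over the list alone; Cdkn2d (−0.42) had a p of 0.0477 with the block, Cdkn1b (−0.31), Cdkn2a (−0.43) and Cdkn2b (−0.47) did not pass, and the median was −0.31 (adjusted p 0.0228; adjusted p = 0.450 with an estimated correlation).

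**Figure D3:**
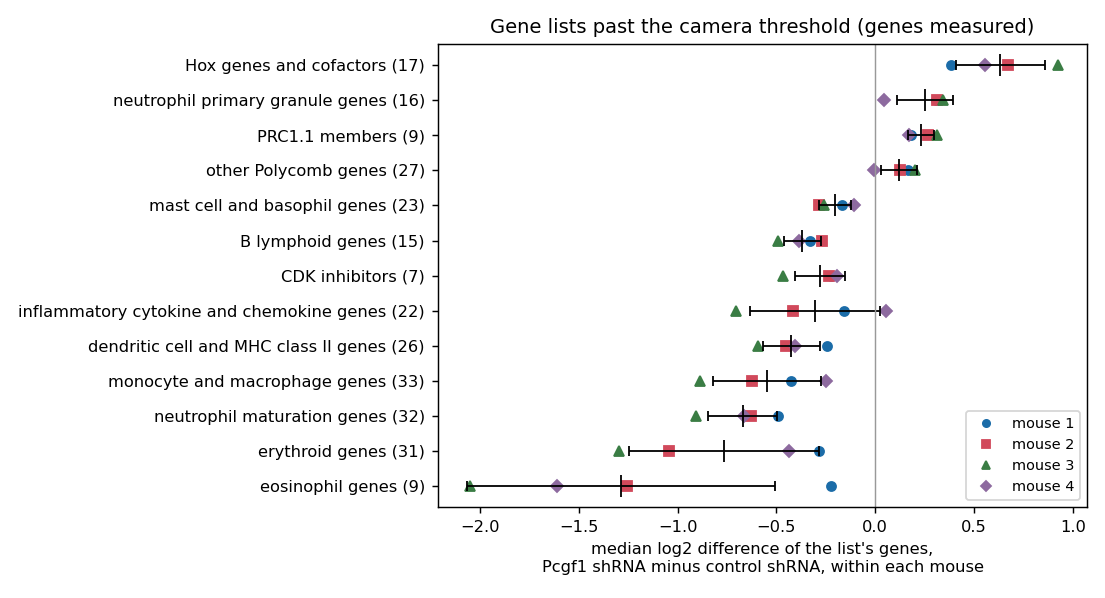
Median log2 difference, Pcgf1 shRNA minus control shRNA, of the genes of each of the 13 lists past the camera threshold, within each mouse (coloured points), with the mean ± SD of 4 mice (black bars). 4 lists lie above 0 and 9 below. The inflammatory list in mouse 4 (0.05) and the list of other Polycomb genes in mouse 4 (−0.01) lie on the opposite side from the other 3 mice.

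In all, 13 of 28 lists passed with the preset correlation, 4 higher and 9 lower, and 12 passed with mouse as a block. With a correlation estimated for each list 0 passed, with a lowest adjusted p of 0.181 without a block and 0.460 with it, so none of the calls holds there. Fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, passed 4 lists: Hox genes and PRC1.1 members (0.00499 each), B lymphoid genes (0.0248) and core binding factor and haematopoietic transcription factors (0.0488). Of these 4 only the Hox list passed fry with mouse as a block (0.0457), against 0.706 for PRC1.1 members, 0.0744 for B lymphoid genes and 0.124 for the transcription factors. The PRC1.1 value includes the fall of Pcgf1, the target of the shRNA, so it does not describe the other members alone. An exact permutation test of the list medians over the 35 splits of the 8 arrays gave p = 0.0286, its smallest, for the Hox, eosinophil and PRC1.1 lists, and the lowest p adjusted over the 28 lists was 0.267. That test takes arrays paired by mouse as exchangeable. It also keeps the filter on dim probes set by the real groups, which can favour the real split.

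Stem and progenitor genes did not move as a list. Of 25 haematopoietic stem cell genes the surface marker Cd34 rose 1.92-fold (3.81 ± 0.08 to 4.75 ± 0.25, n = 4 each, adjusted p 0.0251, block 0.0149), 1 rose adjusted over the list alone, and the list median was 0.02 (adjusted p 0.776; −0.01 with normexp). With the block 3 rose and 2 fell, among them Ctnnal1 (0.62, block 0.0262), Nr4a2 (−0.59, block 0.0375) and Ly6a (−0.68, block 0.0285; chosen after its values were seen), and Erg (0.83) did not pass. Among 29 core binding factor and haematopoietic transcription factor genes Sox4, an HMG box factor of progenitors, rose 1.82-fold (adjusted p 0.0206, block 0.0167), 8 rose and 4 fell adjusted over the list alone, and the median was 0.07 (adjusted p 0.344); with the block 5 rose and 6 fell, among them Gata3 (0.89, block 0.0149) and Id3 (−0.65, block 0.0377). Of 14 T and NK lymphoid genes the kinase gene Lck rose 1.88-fold (adjusted p 0.0339, block 0.0291), 3 rose and 1 fell adjusted over the list alone, with the block 3 rose, among them Thy1 (0.88, 0.0233), and Cd7 fell (−0.58, 0.0442; chosen after its values were seen), Id2 (−0.71) did not pass, and the median was −0.24 (adjusted p 0.776).

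Developmental regulators known as Polycomb targets in stem cells had 19 of their 68 members measured, of which 1 rose, also when adjusted over the list alone. Nkx6-1 (−0.43), Bmp7 (−0.32) and Foxc1 (0.48; −0.04 with normexp) did not pass, and the list median was −0.13 (adjusted p 0.0889). Among 29 p53 target genes Perp, an adhesion and death effector, rose 1.74-fold (adjusted p 0.0264, block 0.0174) and was the 1 call adjusted over the list alone; Pmaip1 (0.40) passed with the block (0.0471), Xpc (0.38) and Fdxr (0.19) did not pass, and the median was 0.01 (adjusted p 0.776).

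For 10 more lists 0 genes passed without a block. Cell cycle genes (42 measured) had a median of 0.00 (adjusted p 0.969), with Ccnd2 at 0.49 (block 0.0301), Myc at 0.48, E2f2 at −0.71 and Ccne2 at −0.24. ATF4 and ER stress genes (27) had a median of 0.02 (adjusted p 0.969; −0.02 with normexp), with Cebpb at −0.35 (block 0.0483; chosen after its values were seen), Ddit3 at −0.51, Shmt2 at 0.24, Psat1 at 0.20 and Psph at 0.22. Cytokine receptor genes (30) had a median of −0.11 (adjusted p 0.353), with Bcl2 at 0.41 (block 0.0342), Osm at 0.51 (block 0.0331), Il10ra at −0.39, Il7r at −1.40 and Stat3 at −0.19, and 1 rose adjusted over the list alone. Megakaryocyte and platelet genes (27) had a median of −0.08 (adjusted p 0.776), with Selp at 0.78, Rgs18 at 0.38 (block 0.0442), Fli1 at 0.23 and Cd9 at −0.64. Stromal and endothelial genes (15) had a median of −0.03 (adjusted p 0.675); Col4a1 (0.90), Thy1, Runx2 (0.35) and Pdgfrb (0.69) were among 6 that rose with the block, and 5 rose adjusted over the list alone.

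Interferon response genes (35) had a median of −0.05 (adjusted p 0.529), with Zbp1 (−0.53) and Gbp3 (0.55) past the block threshold in opposite directions and Gbp2 at −0.36 and Ifi204 at −0.39. Immediate early and heat shock genes (23) had a median of −0.13 (adjusted p 0.0677), with Hspa1a at −1.17, Btg1 at −0.60, Jun at −0.44 and Dusp2 at 0.30. Glycolysis and hypoxia genes (32) had a median of 0.02 (adjusted p 0.776), with Egln3 at 0.61 (block 0.0208), Pdk1 at 0.28, Ankrd37 at −0.26 and Adm at −0.48. Cholesterol synthesis genes (23) had a median of 0.02 (adjusted p 0.529), with Nsdhl at 0.19, Insig1 at 0.19 and Acat2 at −0.23. Ribosomal protein genes (41) had a median of −0.07 (adjusted p 0.0542; 0.02 with quantile normalization), with Rplp2 at −0.18, Rps27 at −0.17, Rplp1 at −0.19 and Rps14 at −0.15 (0.02 with quantile normalization). Adjusted over the list alone 0 genes passed in these 5 lists and in the cell cycle, ATF4 and megakaryocyte lists. The median, the mean and the test differ in sign for the transcription factor, stromal, p53 and ATF4 lists.

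The remaining largest falls belonged to no list. Tmem119, a membrane protein best known from microglia, fell by 1.39 on the log2 scale (SE 0.15, adjusted p 0.0197), Plpp1, a lipid phosphatase, by 1.46 (adjusted p 0.0206), Mgll, which breaks down monoacylglycerols, by 1.32 (adjusted p 0.0458), and Sardh, a mitochondrial sarcosine dehydrogenase, by 1.20 (adjusted p 0.0458, 1 of 4 arrays with the Pcgf1 shRNA above background). All 4 were lower in 4 of 4 mice and passed with mouse as a block (0.0139 to 0.0331).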

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

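The tests of the background correction in the share of rises, of the slide, the signal level and the cell mix in mouse 4, and of dilution and loss of neutrophil-lineage cells in the lineage lists, were chosen only after the results they concern had been seen.

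Other splits of the same samples were run for each count. Without a block 1 of the 35 splits of the 8 arrays, the real one, gave as many as its 132 genes, and the highest other gave 32. This cannot exclude chance, for 2 reasons. The splits take arrays that are paired by mouse as exchangeable. The filter on dim probes was set by the real groups and was not reset for the other splits, which favours the real one. The split with 32 genes set the control arrays of mice 1 to 3 together with the Pcgf1 shRNA array of mouse 1, so it partly followed the real groups, and among the 8 splits that part all 4 pairs of cultures from the same mouse the highest other gave 0, but 8 splits are too few for a share under 0.05. With mouse as a block 1 of 8 assignments within mice, the real one, gave 921 genes and the highest other 0, but 8 assignments are too few for a share under 0.05. For the gene lists chance cannot be excluded: 9 of the 35 splits gave at least the 13 lists of the real split, up to 15, and the highest other among the splits that part all pairs gave 11.

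Rises made up 78.0% of the calls without a block and 54.6% with it. This order depended on mouse 4: without that mouse rises made up 68.3% without a block and 81.4% with it. Without any other single mouse the fit without a block called at most 1 gene, so the shares cannot be compared there. The excess of rises without a block was also found with quantile normalization, so the choice between these scalings does not account for it. With quantile normalization 78.8% of calls were rises (exact 95% interval 71.9% to 84.7%). This interval and those that follow take called genes as independent trials. Genes on the same arrays are correlated, so the intervals do not measure the spread between mice. Among genes above background on all 8 arrays 76.5% were rises (68.4% to 83.5%). This cannot decide on dim probes, since 16410 of the 17301 genes tested were left, with nearly the same calls (101 higher and 31 lower). The genes that rose without a block were dim. Their median control log2 signal was −1.98, against −0.98 for genes that fell and −0.24 for all genes tested. The background correction stays open, since with normexp 66.7% of calls were rises (54.6% to 77.3%), an interval that includes the bound of 60% set for these tests, and 41.4% were with normexp and the block. Genes that fell with the block had a median between-mouse SD 1.73 times that of genes that rose (0.40 against 0.23 log2), but this decides nothing, because genes gained by the block are those whose level differs between mice. For genes with a value on every array both fits give the same log2 change. Their calls therefore differ through the error term, from which the block takes differences between mice. Of the calls with the block, 389 falls and 400 rises were not called without it. Why so many of these were falls stays open.

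Lists of mature blood cells were lower together while the primary granule list was not. Array scaling is argued against, since the neutrophil maturation median was at most −0.58 under quantile normalization, scaling to the median and normexp. A loss of neutrophil-lineage cells of every stage is argued against too, as far as the mixed primary granule list marks early cells. The difference of the list medians, primary granule minus maturation, averaged 0.92 with an SD of 0.24 over 4 mice. An equal dilution of every mature lineage is argued against by the difference of the erythroid and megakaryocyte list medians, which averaged −0.69 with an SD of 0.20 over 4 mice, although taken from the median signal of each list on each array it averaged −0.60 with an SD of 0.30, just short of the bound of 2 SD set for it. Fewer late-stage cells in the knockdown cultures, or lower transcription of these genes within each cell, may each give this pattern and stay open, since cell counts were not used here.

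Both arrays of mouse 4 stood apart on the first component. The slide is argued against, since mouse 3 on the same slide had no array beyond −6.47, on the side of mice 1 and 2 (midpoint 14.96). Signal level stays open: 1 of the 2 arrays of mouse 4 lay inside the range of the 75th percentiles of the other 6 arrays, but the median signal of both (39.4 and 48.6) lay above that of the other 6 (29.1 to 36.6). Of 12 cell marker lists 2 lay above the other 6 arrays by over 0.5 log2 in both arrays of mouse 4, T and NK genes by 0.72 and haematopoietic stem cell genes by 0.67, so another mix of cells in this animal may contribute. The mice differ in other ways, such as their share of each parental strain, that were not tested.

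Single arrays far from the other 3 of their group were found in 16 of 328 groups of named genes and lists, where 16.4 are expected by chance; the ratio given is the gap to the nearest array over the range of the group, tested at Dixon's 95% critical value. Of the 16, 3 fell on the control array of mouse 4 and 5 on its Pcgf1 shRNA array. In the control group the Hoxa9 value of mouse 1 (−1.36, others −2.27 to −2.18) had a ratio of 0.902, and the Hoxa5 value of mouse 2 (−7.21, others −5.71 to −5.44) a ratio of 0.848. Fpr1 in the control array of mouse 4 (−2.49, others −1.35 to −1.12) had a ratio of 0.836 and Rgs18 in the same array (2.41, others 2.02 to 2.04) a ratio of 0.937. Further control values were those of Bcl2 in mouse 1 (ratio 0.886), Cdkn1b in mouse 2 (0.847), Rplp1 in mouse 2 (0.895) and Igfbp4 in mouse 3 (0.859). With the Pcgf1 shRNA they were Mzb1 (0.893) and Tnfaip3 (0.900) in mouse 1 and Shmt2 (0.835), Jarid2 (0.886) and Bcor (0.849) in mouse 4. Among list medians, the primary granule list in the control array of mouse 4 (3.85, others 4.08 to 4.09) had a ratio of 0.969, and in the Pcgf1 shRNA array of mouse 4 the ATF4 list had a ratio of 0.937 and the list of developmental regulators 0.916.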

How the results depend on the processing

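The normexp correction and the settings that join the mouse block with another choice were chosen after seeing the data; the planned normexp on mean signals was not run. Of the named genes and the lists, none that passed without a block changed direction in any setting run, while some that did not pass changed sign, and the calls depend on the test and on the mice they come from. Between the fits without and with the mouse block the camera direction turned for the p53 list (up to down) and the cell cycle list (down to up), which passed in neither. Signal over background limits the folds of 7 of the 103 higher and 1 of the 29 lower genes, which were above background on 0 arrays of 1 group. It may also limit those of genes above background on only some arrays of a group, such as Gdf11, Sardh and Hoxa5. Their changes are given as fitted and not as bounds. Values are total, higher and lower genes. The mouse block gave 921, 503 and 418, mouse as a random block 938, 564 and 374, and array weights 1229, 740 and 489. Slide as a block raised the lower genes to 48, and trend with robust variances raised them to 53. Normexp lowered the total to 72 and the higher genes to 48. A fold of at least 2 left 44, 29 and 15, and an adjusted p of 0.1 gave 321, 212 and 109.

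The filter and the samples ended calls. With no filter on dim probes 0, 0 and 0 of 32969 genes passed (2199 unadjusted), and on slide 1 alone and slide 2 alone 0, 0 and 0 (2372 and 619 unadjusted), where 4 arrays remain in each. Leaving out 1 mouse or 1 array gave 0 to 363 genes, 0 to 248 higher and 0 to 115 lower. It gave 1 gene without mouse 1, 0 without mouse 2 or 3 and 363 without mouse 4; without the control and the Pcgf1 shRNA array of mouse 1 it gave 17 and 27, of mouse 2 1 and 0, of mouse 3 4 and 0, and of mouse 4 150 and 186. With the mouse block, leaving out mouse 1 gave 284, 128 and 156, leaving out mouse 2 0, 0 and 0 (2435 unadjusted), leaving out mouse 3 306, 177 and 129, and leaving out mouse 4 145, 118 and 27. The block gave 922, 561 and 361 with quantile normalization, 1291, 535 and 756 with normexp (41.4% higher against 54.6%), 1050, 559 and 491 with probes above background on all 8 arrays, and 877, 483 and 394 with the deposited value table. Apart from the smaller number of arrays or the larger number of genes tested, the cause was not tested.

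Quantile normalization (170), median scaling (135), all 8 arrays (132), non-uniform spots kept (132), single probes (131), probe means (124), the value table (120) and a fold of 1.5 (112) stayed within 1.5 times the count of 132. Of 136 genes named by the rule 35 passed. All 35 passed with the mouse block, which added 36; 51 were gained with array weights; 2 each were lost with slide as a block, quantile normalization and the value table, 15 with normexp, 35 with no filter, and, with no block, 35 without mouse 1, 2 or 3 and 11 without mouse 4. Of the 22 genes chosen after their values were seen 8 passed without a block, and in that fit all 8 were lost with no filter or without mouse 1, 2 or 3.

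The Pcgf1 level stayed between −1.44 and −1.09 in all settings run, with adjusted p from 0.000635 to 1.00. It did not pass with no filter (−1.36, adjusted p 0.104), on slide 1 alone (−1.40, 0.123) or slide 2 alone (−1.31, 1.00), or with the block and without mouse 2 (−1.34, 0.0896). Without a block it did not pass without mouse 1 (0.113), mouse 2 (0.352) or mouse 3 (0.0904), nor without the control array of mouse 2 (0.0935) or the Pcgf1 shRNA array of mouse 2 (0.0924) or 3 (0.0676). Leaving out mice or arrays gave −1.44 to −1.28. Of the list calls, 0 were left with an estimated correlation, and fry passed 4 lists for a balanced direction and 11 for change either way, against 13; 11 to 16 lists passed in the other settings.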

Other observations

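The 8 genes of the first paragraph were chosen only after their values had been seen.

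Several genes outside the lists and outside the 24 largest changes rose with the Pcgf1 shRNA, each in 4 of 4 mice. Hmga2, an architectural chromatin protein of fetal stem cells, rose 2.11-fold (log2 change 1.08, SE 0.14, adjusted p 0.0206, 0.0149 with mouse as a block), and Zfp521, a zinc finger factor of immature blood cells, 1.68-fold (adjusted p 0.0354). The planar cell polarity genes Vangl2 and Celsr1 rose 2.31-fold and 1.87-fold (adjusted p 0.0270 and 0.0251). Acvr2b, a receptor for Gdf11, rose 1.47-fold (adjusted p 0.0415) beside its ligand gene. Epop, which encodes a protein bound to the other main Polycomb complex, PRC2, rose 2.09-fold (adjusted p 0.0206). The receptor genes Tyro3 and S1pr3 rose 1.97-fold and 1.88-fold (adjusted p 0.0206 and 0.0339). All 8 also passed with mouse as a block, and without a block all 8 lost the call without both arrays of mouse 1, 2 or 3. With the block 5, 8, 2 and 4 of the 8 lost it without mouse 1, 2, 3 or 4.

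Genes that rose were tested for lying side by side in the genome, as genes of a domain released as a whole would. Among 11741 ordered genes 21 adjacent pairs both rose with mouse as a block, 3 of them Hoxa pairs (Hoxa4 with Hoxa5, Hoxa7 with Hoxa9 and Hoxa9 with Hoxa10). Without Hox genes 18 pairs remained against a mean of 12.2 in random relabellings (central 95% interval 6 to 19, one-sided permutation p 0.063), so the excess of the whole set (21 pairs, p 0.016) was not shown outside the Hox genes. Without a block 4 pairs rose (random mean 0.529, p 0.0017), 2 of them Hoxa pairs. Genes that fell lay together more often, with 30 adjacent pairs against a mean of 7.99 (central 95% interval 3 to 14, one-sided permutation p 1e-04, the smallest possible). Of the 30, 18 shared the start of their symbol, such as Fpr1 with Fpr2, S100a8 with S100a9, Prg2 with Prg3 and Ly6a with Ly6c1, in line with families of related genes in the same lineages, or with probes that read more than 1 member of a family.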
